A study of Zea mays with 14 samples.

How the data were processed

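Digital gene expression (tag) profiles were measured in leaf and root of maize at the three-leaf stage. The plants were wild-type DH4866 or DH4866 carrying ZmPIS, a phosphatidylinositol synthase gene, in sense or antisense orientation. Per the labels, poly(A) RNA was captured on oligo(dT) beads, cut at CATG with NlaIII and trimmed with MmeI to tags of CATG plus 17 bases, which were sequenced at 35 bases. Each of the 14 combinations of tissue, genotype and treatment had 1 library. The treatments were normal growth and 18% polyethylene glycol (PEG) for 24 or 72 h, and the antisense line was profiled at 24 h of PEG alone.

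For each library the authors deposited a table of distinct tags. Per the file headers its copy number column holds counts, and these were whole numbers of 2 or more, so tags seen once are not listed. The deposited TPM column is the copy number scaled to the sum of the listed copies of the library, as its values equalled that ratio to within 0.005. The authors' tag cleaning was not given in the sources used here, nor was any aligner or genome build. Library totals ran from 5531798 to 6052234 listed copies. Copies without molecular identifiers are not independent molecules, so any precision drawn from them covers counting error only.

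The reference at hand listed 49888 maize genes without sequences or product names, so tags could not be assigned to genes. Tags therefore replace genes throughout, ZmPIS itself was not analysed here, and the 39 gene lists fixed before the data were examined could not be tested. Copy numbers were joined into 1 matrix of 578364 distinct tags, with an unlisted tag entered as 0. Levels were computed as counts scaled in that way and are given as CPM.

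Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) on tags with at least 10 copies in at least 2 libraries. The adjusted p values are Benjamini-Hochberg values, and a tag was called at an adjusted p under 0.05. The 12 wild-type and sense libraries entered an additive fit with treatment and genotype effects in each tissue, which left 4 residual degrees of freedom. In that fit the wild-type and sense libraries of a treatment stand in as repeats of each other, so a real difference between the lines in their response counts as error. The sense effect over both tissues used 1 sense term and left 5 degrees of freedom. The comparison of root with leaf used 14 libraries in 7 matched pairs and left 6. The difference between the lines in their PEG response added a sense term at 24 h and one at 72 h, shared by both tissues and tested together, which left 2. No paired analysis was possible by replicate number because each group had 1 library. The p values measure only the spread between single libraries, and nothing in the labels says that the libraries came from separate cultures or plants. A standard error (SE) is the log2 fold change divided by the square root of its F statistic.

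The antisense line had 1 library per tissue and was given no p. Tags were counted as apart where CPM plus a pseudocount of 1 differed at least 4-fold and the higher level was at least 20 CPM. The sense line was counted the same way beside it. The exact test of paired libraries was a two-sided permutation of the tissue labels within pairs.

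The tags named in each comparison followed a rule written before the data were examined. Where tags were called, the 5 higher and the 5 lower of largest absolute log2 fold change were taken, among called tags with at least 20 CPM on the higher side and 1 direction in every matched pair. Where none was called, the 5 higher and 5 lower of smallest p with 1 direction in every pair were taken, as tags that did not pass. Tags outside the rule are said to have been chosen after their values were seen. The files list no tag below 2 copies, so for a tag unlisted in 1 arm no fold change is given, only the levels.

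The fits were tested on simulated data with the same layout and 200 changed tags of at least 50 copies on average. At a dispersion of 0.05, the comparison of leaf at 72 h with control recovered 82.1% of 4-fold and 98.5% of 8-fold changes. At a dispersion of 0.2 it recovered 0% and 6.06%, while the sense effect recovered 10.4% and 62.1% in root and 70.1% and 100% over both tissues. The common dispersion of the real 12-library fit was 0.17.

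Alternatives fixed before the data were examined were other scaling (RLE), no low-count filter, limma-voom (limma 3.58.1), DESeq2 1.42.0, a separate fit for each tissue, all 14 libraries, no genotype term, no treatment block, each library left out in turn, and other thresholds for the antisense counts. Those chosen after seeing the data were scaling by library size only, at least 100 copies in 2 libraries, edgeR's legacy dispersion, removal of adaptor tags, merging of tags 1 mismatch from a tag at least 20 times as abundant, TMM-scaled CPM for the antisense counts, other settings of the correlations across tags, and the 4 pairs other than leaf at 24 h and root control. DESeq2 used its Wald test, or a likelihood ratio test for the sense response to PEG. Neither allows for the few residual degrees of freedom as the F test does, so the p values are not on 1 footing. Labels were exchanged under the reported edgeR setting alone, so calls under other settings lack that check. Computation used R 4.3.3 (with the data.table package) and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.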

Results

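Tag profiles were collected from 7 leaf and 7 root libraries of maize, 1 library for each combination of tissue, genotype and treatment. In each tissue the wild type and the ZmPIS sense line were profiled under normal growth (control) and after 24 and 72 h in 18% PEG, an osmotic agent that lowers water availability. The antisense line was profiled after 24 h of PEG. The series sets out to compare the transcript profiles of wild-type and ZmPIS transgenic maize in connection with drought tolerance. No group had replicates, so values below are single libraries unless a number of libraries is given. The libraries held 5531798 to 6052234 listed copies and 578364 distinct tags between them, of which 42237 were listed in every library and 291009 in 1 library. Leaf libraries held 106552 to 149261 distinct tags and root libraries 157029 to 209965. The root library had more in 7 of 7 matched pairs (exact permutation test, two-sided, p = 0.0156).

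Root and leaf were compared in 7 pairs matched on genotype and treatment. The most abundant leaf tag, CATGCATCAGCAGTGTGTACC, stood at 21370 ± 4150 CPM in leaf (SD, 7 libraries) and at 747 ± 491 CPM in root. The tag CATGCTGTTTTGTAATAATTA stood at 8085 ± 1490 CPM in leaf and 0.936 ± 0.714 CPM in root. In contrast, CATGTTGGTTGATCCGATTGC was the most abundant tag of root at 14150 ± 6010 CPM and was also abundant in leaf at 10880 ± 2670 CPM. These 3 tags were chosen after their values were seen, for their abundance. Among the tags taken by the naming rule, CATGCTGTTTTGTAATAAAAA (568 CPM), CATGCAGACTTCCCAGGTAGC (418 CPM), CATGCGAGATACTGTAACAAC (411 CPM) and CATGTAACGGTTAGGACTTGC (345 CPM) were listed in 7 of 7 leaf libraries and in no root library, with adjusted p from 1.83e-08 to 2.4e-08. The tag CATGCAATAAATAAAGTGACT averaged 937 CPM in leaf and was listed in 1 root library, the wild-type control, at 0.342 CPM (adjusted p = 1.56e-10, higher in leaf in 7 of 7 pairs). On the root side, CATGTCAGTCTATGAATGAAA (531 CPM), CATGATTCGTTCAATAAATGA (482 CPM), CATGCCATTGCGCGTGTTCAC (459 CPM) and CATGTAATGTTGAATTATTAT (354 CPM) were listed in 7 of 7 root libraries and in no leaf library, with adjusted p from 3.15e-08 to 4.58e-08. The tag CATGTTGATGAGCAGCTTTCG averaged 1199 CPM in root and was listed in 1 leaf library, wild type at 72 h, at 0.354 CPM (adjusted p = 2.5e-10).

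The tissue difference reached most of the tags tested. Of 77934 tags, 26864 were higher in root and 20917 were higher in leaf, together 61.3%. The sets listed in all 7 libraries of 1 tissue and in none of the other held 3886 leaf tags and 5024 root tags. Of these, 177 leaf tags and 248 root tags averaged at least 20 CPM, and the 2 sets took 0.902 to 1.11% and 0.972 to 1.8% of the copies of their libraries. Scaling by library size alone moved the median log2 difference of all tags by 0.60 toward root and gave 38470 tags higher in root and 15663 higher in leaf, and a filter of at least 100 copies in 2 libraries left 12262 called.

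PEG for 72 h was set against normal growth in leaf to find the tags that differ under osmotic stress. Each line had 1 control library per tissue, shared by 24 and 72 h, and its labels give no sampling time. A change with time under normal growth therefore cannot be told apart from an effect of PEG. Tags that were scarce in unstressed leaf rose to a high level in both lines. CATGTATATATACAAAAACAT rose from 2.02 CPM in the wild-type and 0.352 CPM in the sense control to 327 and 176 CPM, a log2 fold change of 7.92 ± 0.97 (SE; adjusted p = 0.0185). CATGTTCGTGAGAGAGGTGGT rose from 2.19 and 0.705 CPM to 176 and 148 CPM (log2 fold change 7.03 ± 0.62, adjusted p = 0.0127), and already stood at 60.7 and 72.0 CPM at 24 h. CATGTAATTTTGATCGAATAA rose from 11 copies in the wild-type control and none listed in the sense control to 1052 and 255 copies (adjusted p = 0.0286); no fold change is given, since without the wild-type control the control arm is unlisted. CATGGTGATTCCTTAAAAAAA (adjusted p = 0.0189) went from at most 2 copies in a control library to 363 and 216, and CATGTCTGTCTTTCCTTTTTT (adjusted p = 0.0303) from at most 4 copies to 415 and 266.

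Other leaf tags fell over the same 72 h. CATGCGACCAAGTCAAGGGAG, at 24.0 CPM in the wild-type and 19.2 CPM in the sense control, was unlisted in both libraries at 72 h (adjusted p = 0.0185). CATGACCCAAGCAAGGAAGGA fell from a mean of 23.1 CPM to 0.602 CPM (log2 fold change -5.02 ± 0.61, adjusted p = 0.0191). CATGCATTTGCTCTCTCCGAT fell from 88.1 to 2.87 CPM (-4.70 ± 0.78, adjusted p = 0.0441). CATGCAAACCGATGAATCTAT (-4.93 ± 0.81, adjusted p = 0.0285) and CATGTGAAACACACAGCTGCT (-4.86 ± 0.83, adjusted p = 0.0253) fell to a mean of 0.690 and 0.773 CPM. All of these tags changed in the same direction in both lines, as the naming rule required.

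**Figure D1:**
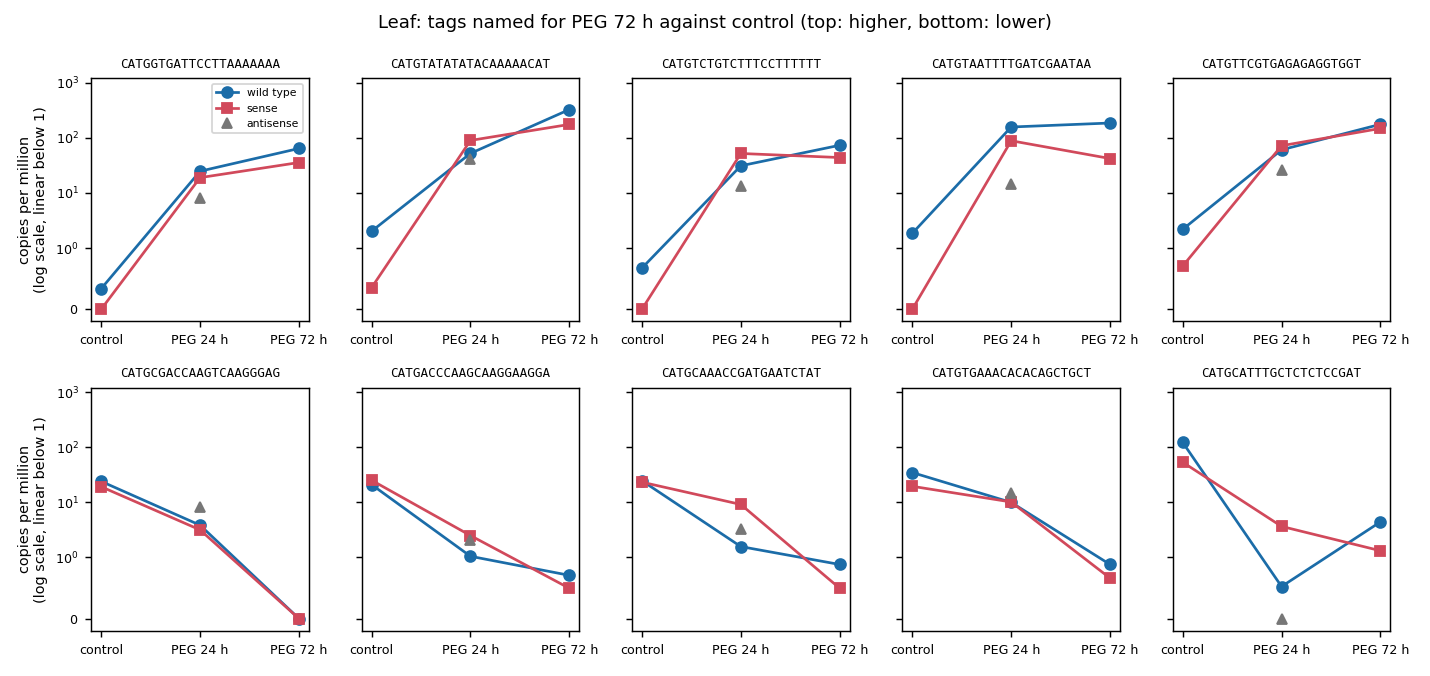
Level of the 10 named leaf tags in CPM (y axis, log scale, linear below 1) under control, PEG 24 h and PEG 72 h (x axis). Circles are wild-type, squares sense and the triangle the antisense library, each point being 1 library and an unlisted tag drawn at 0; CATGTATATATACAAAAACAT stood at 327 and 176 CPM at 72 h and CATGCGACCAAGTCAAGGGAG was unlisted there.

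In leaf at 72 h, edgeR called 580 of 75382 tags, 435 higher and 145 lower than control, and 10589 tags had an unadjusted p under 0.05. Each of the 435 and each of the 145 had 1 direction in both lines. The fit takes its error from disagreement between the lines, so calling favours such tags and this is not separate evidence. The median absolute log2 fold change was 3.48 among the higher and 3.36 among the lower tags, or 3.44 and 3.31 with unlisted arms set to 3 copies per library. Among the higher tags 26 were unlisted in both controls, and among the lower 16 were unlisted in both 72 h libraries. With a single library of an arm left out, the fit called 0 tags, whether the leaf control or the leaf 72 h library of the wild type or of the sense line was removed. Leaving out a root library gave 142 (wild type at 24 h), 158 (sense at 24 h), 295 (wild type at 72 h) and 362 (sense at 72 h), and scaling by library size alone, which moved the median of all tags by -0.125, gave 232 higher and 154 lower. DESeq2 called 1998, limma-voom 1198, the fit of leaf alone 1090 and the fit without a genotype term 1744.

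At 24 h of PEG in leaf, edgeR called 0 tags, with 6116 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0675. All 10 tags named here had that adjusted p and did not pass with edgeR. CATGTTCGTGAGAGAGGTGGT, named above at 72 h, stood at a mean of 66.4 CPM at 24 h against 1.45 CPM in control (log2 difference 5.53 ± 0.60). CATGAACGGCGCCGGGTCGTG stood at 129.7 against 1.77 CPM (6.34 ± 0.78), CATGTAGCGTTGGAGATAGTA at 54.5 against 3.14 CPM (4.28 ± 0.51), CATGGCGAGGGCCGACGGTGA at 41.3 against 2.74 CPM (3.93 ± 0.48) and CATGGCGTCCAAAAAAAAAAA at 30.25 against 0.420 CPM. On the lower side, CATGTATATGCTAAAGAAAAT stood at 1.94 against 77.2 CPM (-5.34 ± 0.54), CATGAAGCGCATCTCCGTCAT at 10.5 against 129.6 CPM (-3.66 ± 0.48), CATGTGAATTTCAGATAAATA at 4.63 against 111.7 CPM (-4.68 ± 0.61), CATGTGTTACTATTACTGAAT at 1.61 against 42.1 CPM (-4.74 ± 0.53) and CATGGTCATAGAACCTCCAGC at 2.21 against 36.6 CPM (-4.03 ± 0.48). Each had the stated direction in both lines, as the naming rule required. Other fits called these 10 tags and others: DESeq2 722, limma-voom 135, the fit without a genotype term 226, the fit without a low-count filter 189 and the filter of at least 100 copies 78.

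The later and the earlier time point in leaf were compared directly. Among called tags, CATGTTCCATCAGGCAAGCTT rose from 2.27 and 4.99 CPM at 24 h (wild type, sense) to 111 and 134 CPM at 72 h (log2 fold change 5.38 ± 0.56), with 26.1 and 47.4 CPM in the controls. CATGGTCATAGAACCTCCAGC rose from 2.10 and 2.33 CPM to 38.4 and 41.8 CPM (4.40 ± 0.48), with 29.1 and 44.1 CPM in the controls. CATGGGTTATTAAACTTCTTC (4.38 ± 0.47), CATGGGTTATTAAACTTCAAA (4.44 ± 0.50) and CATGAGATATCACTTTTTCAG (4.18 ± 0.48) also rose between 24 and 72 h. Each of these had an adjusted p of 0.0491 and rose in both lines, as the naming rule required. edgeR called 8 tags higher and 0 lower at 72 h, with 6309 at an unadjusted p under 0.05, against 600 by DESeq2 and 41 by limma-voom. The count was 0 with any 1 of the 12 libraries left out, with all 14 libraries fitted, with leaf fitted alone and with library size scaling, which moved the median by -0.193; without a genotype term it was 217, without a filter 127 and with at least 100 copies 24.

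In root, PEG for 24 h was set against normal growth in the same way, again with controls shared by both times. Tags absent or nearly absent from unstressed root appeared within 24 h in both lines. CATGGCGGATTCGTGGAGCTG was unlisted in both controls and stood at 28.0 CPM in wild type and 33.3 CPM in the sense line, and CATGGGTCTTCTTGTGCATCC, also unlisted in both controls, at 23.4 and 27.5 CPM. CATGGGTCTTCTTGTGCAAAA went from 3 copies in the wild-type and none listed in the sense control to 373 and 496 copies. CATGTAGCTTTTGGGGTTTTC went from 3 and none listed to 395 and 308 copies, and CATGGCGTTGTCTGACGAAAC from 2 and none listed to 263 and 354 copies. On the lower side, CATGTGGTGTTGTGCAAAAAA fell from 37.5 and 33.2 CPM to none listed and 0.352 CPM (adjusted p = 0.0103). CATGTGTTAATTTAGTAGTAA fell from a mean of 27.2 to 1.38 CPM (log2 fold change -4.25 ± 0.55) and CATGTGTGACAATCTCCTAAT from 20.9 to 2.24 CPM (-3.08 ± 0.47). CATGTAGATATTCACCTCGAG stood at 26.2 and 210.3 CPM in the controls and was unlisted in all 5 root libraries under PEG. Except for CATGTGGTGTTGTGCAAAAAA, each tag named here had an adjusted p of 0.0491, and all had 1 direction in both lines, as the naming rule required.

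The antisense root library at 24 h, which was not in the fit, also listed the named tags that were higher under PEG. It held CATGGCGGATTCGTGGAGCTG at 18.3 CPM, CATGGGTCTTCTTGTGCATCC at 12.8 CPM, CATGGCGTTGTCTGACGAAAC at 15.4 CPM, CATGGGTCTTCTTGTGCAAAA at 48.4 CPM and CATGTAGCTTTTGGGGTTTTC at 30.5 CPM. No test against the controls was made with it, since the tags were chosen for their low level in the same controls. Of all 60 tags higher in root at 24 h, 55 were unlisted in all 7 leaf libraries. The share among all tested tags was not computed, so a response particular to root cannot be read from this.

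**Figure D2:**
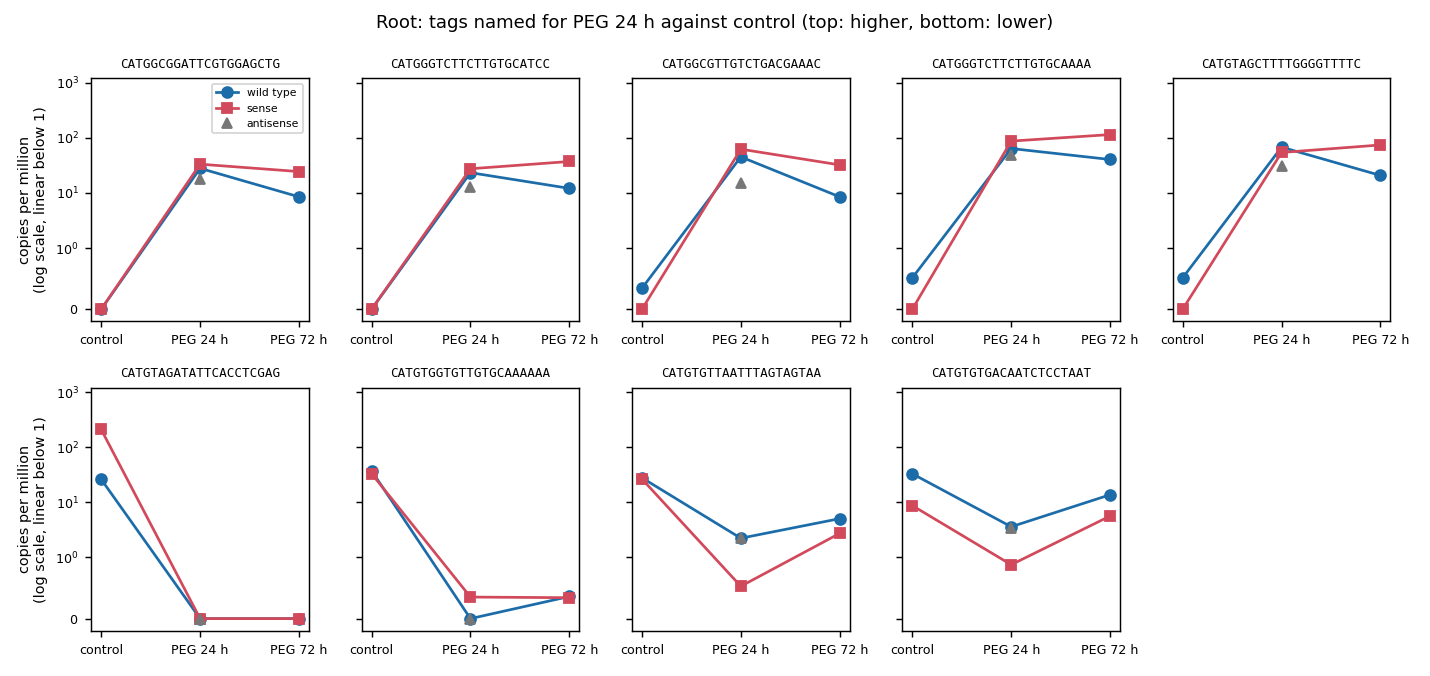
Level of the 9 named root tags in CPM (y axis, log scale, linear below 1) under control, PEG 24 h and PEG 72 h (x axis). Circles are wild-type, squares sense and the triangle the antisense library, each point being 1 library and an unlisted tag drawn at 0; the 5 tags of the upper row, among them CATGGGTCTTCTTGTGCAAAA at 64.04 and 87.4 CPM at 24 h, stood at no more than 0.513 CPM in the controls.

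In root at 24 h, edgeR called 66 tags, 60 higher and 6 lower, with 5733 at an unadjusted p under 0.05. The median absolute log2 fold change was 6.06 for the higher and 5.80 for the lower tags, or 5.39 and 4.29 with unlisted arms set to 3 copies per library. The count was 0 or 1 when any 1 of the 12 wild-type and sense libraries of either tissue was left out. Library size scaling gave 0 higher and 1 lower, all 14 libraries 1, the filter of at least 100 copies 0 and legacy dispersion 21, whereas limma-voom called 2466, DESeq2 230, root fitted alone 1140, the fit without a genotype term 461 and no filter 1185.

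At 72 h in root, CATGTGGTGTTGTGCAAAAAA was the 1 tag called. It fell from 37.5 CPM in the wild-type and 33.2 CPM in the sense control to 0.362 and 0.342 CPM (log2 fold change -6.47 ± 0.74, adjusted p = 0.0159). It was lower in both lines, as the naming rule required. edgeR gave 5441 tags an unadjusted p under 0.05, DESeq2 called 364, limma-voom 2331, root fitted alone 539, no filter 876, no genotype term 262 and the filter of at least 100 copies 5, and legacy dispersion called 0. Without the sense root library at 72 h the count was 78, though not with this tag (adjusted p = 0.0639). It was 0 without any 1 leaf or root control, leaf 72 h library or root 24 h library of either line, or without the wild-type root library at 72 h, with adjusted p for this tag from 0.0648 to 0.561.

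Between 24 and 72 h in root, edgeR called 0 tags, with 2740 at an unadjusted p under 0.05 and a smallest adjusted p of 0.59, against 28 by DESeq2, 90 by limma-voom and 27 without a filter. Those 2740 were below a share of 0.05 of the 75382 tags tested, which p values at their nominal level reach with no effect. Whether they hold that level in this fit was not tested, so the count does not show that no tag changed. The tags of smallest p did not pass with edgeR as reported, though DESeq2 called CATGTGGTAATCTAAACCAGT, CATGTCCTTCGTTGAGAAATA and CATGCAAGGAAACCACATAAA, and limma-voom called CATGATAATTGGTTTTAATGA. In the order given, these tags passed under 3, 2, 1 and 2 of 12 other settings. The first of them also passed with limma-voom and with edgeR without a filter. CATGTGGTAATCTAAACCAGT averaged 171 CPM at 72 h and 3.56 CPM at 24 h (log2 difference 5.59 ± 0.72), and CATGATAATTGGTTTTAATGA averaged 46.2 and 0.352 CPM. CATGTCCTTCGTTGAGAAATA averaged 11.1 CPM at 72 h and 74.9 CPM at 24 h (-2.74 ± 0.45, adjusted p = 0.598), and CATGCAAGGAAACCACATAAA averaged 17.4 and 86.2 CPM (-2.39 ± 0.39, adjusted p = 0.598).

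Whether PEG acted differently in root and leaf was tested as the difference of the effects. CATGCAAAATGTAAATAAAAC had the smallest adjusted p at 72 h, 0.0691, and did not pass with edgeR as reported (root minus leaf 5.97 ± 0.58 on the log2 scale). It passed under 5 of 11 other settings. These were DESeq2 (2e-20) and edgeR with legacy dispersion, without a filter, with at least 100 copies and without a genotype term. CATGTAGCGTTGGAGATAGTA had a root minus leaf value of -5.89 ± 0.70 at 72 h (adjusted p = 0.139) and -5.38 ± 0.69 at 24 h (adjusted p = 0.296). It passed at neither time with edgeR as reported. It passed at both with DESeq2 (2.06e-10 and 2.79e-08) and with edgeR without a filter, and at 72 h also without a genotype term. In leaf it stood at 5.04 and 1.23 CPM in the controls and at 56.3 and 52.7 CPM at 24 h, and in root at 14.0 and 13.8 CPM in the controls and 5.84 and 6.17 CPM at 24 h. CATGGTCATAGAACCTCCAGC, low in leaf at 24 h, stood at 16.6 and 22.5 CPM in the root controls and 36.2 and 27.8 CPM at 24 h (4.87 ± 0.62, adjusted p = 0.296 with edgeR and 4.43e-09 with DESeq2). The same tag also passed at 24 h with edgeR without a filter. Each of these had 1 direction in both lines, as the naming rule required. edgeR called 0 tags at 24 h and 0 at 72 h, with 2730 and 6366 at an unadjusted p under 0.05. Of 75382 tags tested, 2730 was below and 6366 above a share of 0.05, which p values at their nominal level reach with no effect. Whether they hold that level here was not tested, so neither count shows the absence or presence of an effect. DESeq2 called 97 and 550, and limma-voom 0 and 0. No filter gave 5 and 24, and at 72 h the fit without a genotype term gave 14. Library size scaling moved the median difference by -0.122 at 24 h and 0.163 at 72 h.

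The sense line was set against the wild type within each treatment to find tags that differ between the lines. With 1 sense line, an effect of the transgene cannot be told apart from one of the line background. In root, CATGAAGTACGGCTGGACGGC stood at 129.5 ± 44.2 CPM in wild type (SD, 3 libraries, 501 to 1014 copies) and at 2.15 ± 0.113 CPM in the sense line (3 libraries, 12 to 13 copies). This was a log2 fold change of -5.82 ± 0.50 (SE; adjusted p = 0.0222), lower in 3 of 3 pairs. The antisense root library held it at 59.3 CPM. In leaf the same tag stood at 18.2 ± 15.7 CPM in wild type and 10.6 ± 3.20 CPM in the sense line (adjusted p = 1), and the difference of its sense effect between root and leaf, -5.32 ± 0.64, did not pass with edgeR (adjusted p = 0.467) but did with DESeq2 (1.94e-10) and with edgeR without a filter (0.0127). CATGTTTTAACGTTATCGGAT stood at 30.3 ± 7.53 CPM in wild-type and 1.98 ± 0.826 CPM in sense root (-3.89 ± 0.42, adjusted p = 0.104, lower in 3 of 3 pairs), and at 82.9 ± 24.2 and 94.2 ± 20.3 CPM in leaf. CATGACGTTCGTGGATGGCGC stood at 6.73 ± 1.28 and 0.290 ± 0.268 CPM in root (adjusted p = 0.232) and at 24.2 ± 20.1 and 27.9 ± 17.6 CPM in leaf. edgeR called neither in root, whereas DESeq2 called both (adjusted p = 2.05e-15 and 7.53e-05), and CATGTTTTAACGTTATCGGAT also passed without a filter (0.00504), with at least 100 copies (0.0391) and without a treatment block (0.0267). For these tags the difference between root and leaf had an adjusted p of 0.467 and 0.876 with edgeR and of 3.94e-09 and 0.00189 with DESeq2.

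Over both tissues, CATGAAAGCTGTCAGAGTTTA was the 1 tag called. It was lower in the sense line in 6 of 6 pairs, at 3.77 ± 2.23 CPM in wild-type and 0.508 ± 0.168 CPM in sense leaf, and 6.34 ± 1.70 and 0.753 ± 0.267 CPM in root (log2 fold change -2.93 ± 0.31, adjusted p = 0.00744). The sense libraries held 2 to 4 copies of it in leaf and 3 to 6 in root, near the lowest listed number of 2. Over both tissues it lies below the 20 CPM of the naming rule and was chosen after its values were seen. In leaf alone, where none was called, the rule did take it. CATGATGCCAGTGGCAACTAG, chosen after its values were seen, was unlisted in all 6 wild-type libraries. It had 21 to 28 copies in sense leaf, 78 to 121 in sense root, and 29 and 103 in antisense leaf and root. With an adjusted p of 0.0546 it was not called by edgeR, but it passed with DESeq2 (1.03e-10), limma-voom (0.00183), no filter (3.01e-23), no treatment block (0.00289) and RLE scaling (0.0497). CATGTTAACATATTTTGTATG had 0 to 2 copies in wild-type leaf and 15 to 55 in sense leaf, and 8 to 18 and 68 to 93 in root (adjusted p = 0.0546, not called by edgeR). Over both tissues it was also chosen after its values were seen, though the rule took it in leaf alone. It passed with DESeq2 (0.000248), no filter (3.75e-11) and RLE scaling (0.0497), and not with limma-voom (0.482).

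**Figure D3:**
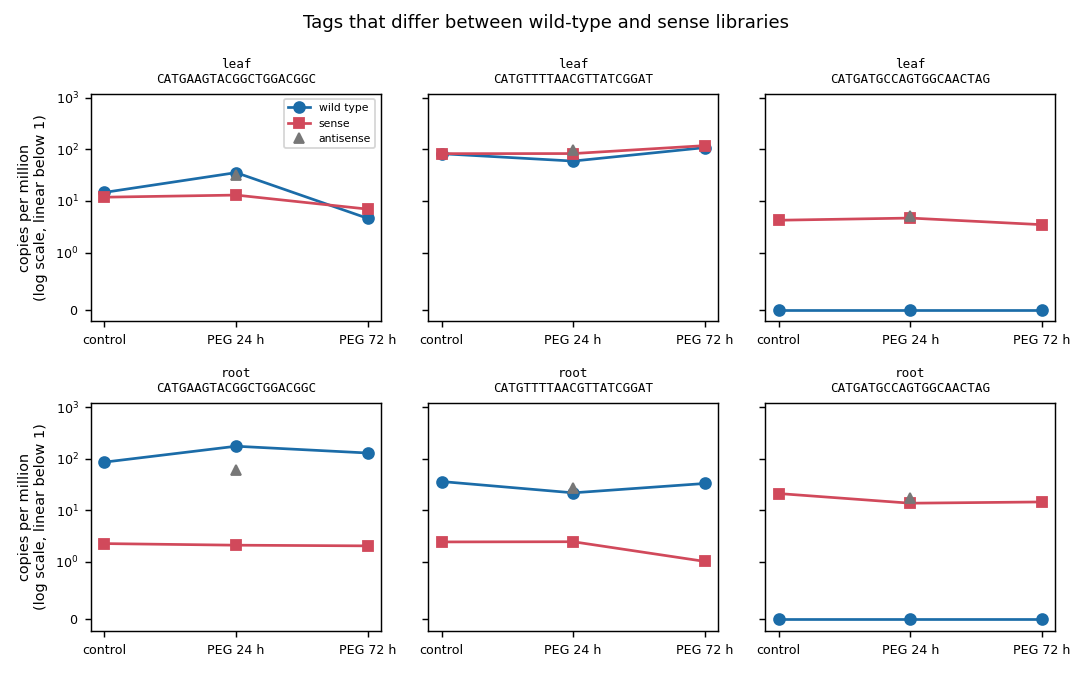
Level of 3 tags in CPM (y axis, log scale, linear below 1) under control, PEG 24 h and PEG 72 h (x axis) in leaf (top) and root (bottom). Circles are wild-type, squares sense and the triangle the antisense library, each point being 1 library and an unlisted tag drawn at 0; in root CATGAAGTACGGCTGGACGGC averaged 129.5 CPM in wild type and 2.15 CPM in the sense line, and CATGATGCCAGTGGCAACTAG was unlisted in all 6 wild-type libraries.

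For sense against wild type, edgeR called 0 tags in leaf, 1 in root and 1 over both tissues, and 0 differed between root and leaf. Of 75382 tags tested, 1427, 1963, 2485 and 1455 had an unadjusted p under 0.05, in the same order. Each count was below a share of 0.05, which p values at their nominal level reach with no effect. With the genotypes of some pairs exchanged, however, the fit gave 889 to 7509 such tags in leaf and 1803 to 7228 in root. That share is therefore no fixed reference here, and a count below it does not show that no tag differed. DESeq2 called 1, 20, 19 and 14, and limma-voom 2, 2, 1 and 0, where the limma-voom tag over both tissues was not CATGAAAGCTGTCAGAGTTTA (adjusted p = 0.0836, the highest for this tag over 10 other settings, the lowest being 2.01e-06). The root call of CATGAAGTACGGCTGGACGGC ended without the leaf control of either line (adjusted p = 0.106 wild type, 0.105 sense) or without any root library, with adjusted p from 0.19 to 0.496; the other counts moved with the filter (44 in root and 1154 over both tissues without one, 2 in root minus leaf), and the count in root minus leaf was 1 without the wild-type or the sense root library at 72 h. The call of CATGAAAGCTGTCAGAGTTTA held without the wild-type or the sense root control (3 tags called each) and ended without any 1 of the other 10 libraries, with 4 pairs only and with legacy dispersion, at adjusted p from 0.0587 to 0.12; RLE scaling gave 3 higher and 2 lower.

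Whether the sense line responded to PEG differently from the wild type was tested at 24 and 72 h jointly, over both tissues. edgeR called 0 tags, with 2836 at an unadjusted p under 0.05 and a smallest adjusted p of 1, against 11 by DESeq2, 0 by limma-voom and 4 with legacy dispersion. Those 2836 were below a share of 0.05 of the 75382 tags tested, the share reached with no effect. The responses of both lines were also correlated across 9213 tags of at least 20 CPM on average, which are not independent replicates. Pearson's r was 0.851 in leaf at 72 h and 0.304 in leaf at 24 h, and 0.0932 and 0.132 in root at 24 and 72 h. Spearman's rho was 0.808, 0.199, -0.0936 and -0.0944 in the same order. A pseudocount of 5 moved r in root to 0.052 and 0.066, and taking tags of at least 5 CPM moved it to 0.153 at 24 h.

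The antisense line was set against the wild type at 24 h of PEG, the 1 treatment it shares with the others. In root, CATGAAAGGTTGATTTCAGGC had 805 copies in the antisense and 2 in the wild-type library, and CATGTGTGGATTGTATATATA had 801 and 3. CATGGTCGAGGAGAAGGCCCG had 398 copies and none listed. The sense root library, however, also held these tags, at 721, 469 and 169 copies, and wild-type root at 72 h held them at 49.5, 65.1 and 15.0 CPM. CATGCAATTGCGTGCGGAAGA stood at 11.1 CPM in antisense and 425 CPM in wild-type root, but the other wild-type root libraries held it at 15.6 CPM (control) and 18.4 CPM (72 h). In leaf, CATGGCGACAAATATGTTAGA stood at 58.2 CPM in the antisense and 3.32 CPM in the wild-type library, against 56.1 CPM in the wild-type control and 20.5 CPM in wild type at 72 h. CATGGTTTCGCATTAAAAAAA stood at 40.6 CPM in antisense and 2.62 CPM in wild-type leaf, against 6.555 and 16.45 CPM in wild type at control and 72 h. CATGGTGACTGGCGGGAGGAA stood at 1.92 CPM in antisense and 33.6 CPM in wild-type leaf, but the wild type held it at 2.02 CPM at control and 1.59 CPM at 72 h. These tags were chosen by size after their values were seen.

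In leaf, 35 of 8728 tags were at least 4-fold apart between the antisense line and the wild type, 6 higher and 29 lower. In root 211 of 11073 were, 112 higher and 99 lower. Counted the same way, the sense line differed from the wild type by 203 tags in leaf (135 higher, 68 lower) and 188 in root (140 higher, 48 lower). The libraries also differed in their distinct tags. Wild type, antisense and sense held 118483, 120821 and 149261 in leaf, and 168980, 190929 and 157029 in root. Whether this bears on the counts was not tested, so they do not rank the lines by their distance from the wild type. With 1 library on each side no test was run, and the counts moved with the limits used, as 4-fold at 5 CPM gave 108 and 646 for the antisense line in leaf and root, and a pseudocount of 5 gave 18 and 115. The split by direction moved too. At 2-fold the antisense line had 176 higher and 290 lower in leaf and 869 and 941 in root, and the sense line 745 and 773 in leaf and 755 and 861 in root. On TMM-scaled CPM the 4-fold counts were 8 higher and 42 lower in leaf and 104 and 68 in root for the antisense line, and 145 and 118 in leaf and 131 and 31 in root for the sense line.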

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

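Tests chosen only after the results were seen were library size scaling, the filter of at least 100 copies, legacy dispersion and adaptor removal. So were merging of tags 1 mismatch apart, the 4 pairs only, TMM-scaled CPM and the other settings of the correlations across tags. Comparisons below are PEG at 24 or 72 h against control, 72 h against 24 h, sense against wild type, and root minus leaf for differences of effects. The cause of each change was not tested, except where fewer tags or libraries were used by construction.

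Among 37 named results past the threshold (a tag in a comparison), 351 of 412 values under other settings stayed past it in the same direction, 61 kept the direction without passing and 0 reversed. With 1 library left out, 140 of 140 values stayed past it for root against leaf but 75 of 322 for the PEG and sense comparisons, among them 65 of 120 for leaf at 72 h, 2 of 106 for root at 24 h and 0 of 60 for 72 h against 24 h in leaf, and 0 reversed. A lone library left in an arm is then assumed to vary like the other groups. Counts with any 1 library left out ran from 0 to 544 for leaf at 72 h, 0 to 1 for root at 24 h, 0 to 78 for root at 72 h, 0 to 0 for 72 h against 24 h in leaf, 0 to 1 for sense in root, 0 to 1 for sense in root minus leaf, and 0 to 3 for sense over both tissues.

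DESeq2 called 722 tags in leaf and 230 in root at 24 h, 1998 and 364 at 72 h, and 600 and 28 between 72 and 24 h. It called 1 for sense in leaf, 20 in root, 19 over both tissues and 14 in root minus leaf, 97 and 550 for PEG in root minus leaf at 24 and 72 h, and 11 for the sense response to PEG. Limma-voom called 135 in leaf and 2466 in root at 24 h, 1198 and 2331 at 72 h, 41 and 90 between 72 and 24 h, and 2 for sense in leaf and 2 in root.

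Without a low-count filter the counts were 189 in leaf and 1185 in root at 24 h, 876 in root at 72 h, 127 and 27 between 72 and 24 h, 44 for sense in root, 1154 over both tissues, 2 for sense in root minus leaf, and 5 and 24 for PEG in root minus leaf. With at least 100 copies they were 78 in leaf and 0 in root at 24 h, 5 in root at 72 h, 24 between 72 and 24 h in leaf, 2 for sense in root, 0 over both tissues, 1 for PEG at 72 h in root minus leaf and 12262 for root against leaf. Without a genotype term they were 226 and 461 at 24 h in leaf and root, 1744 and 262 at 72 h, 217 between 72 and 24 h in leaf and 14 for PEG at 72 h in root minus leaf.

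Separate fits for each tissue called 1090 in leaf and 539 in root at 72 h, 1140 in root at 24 h and 0 between 72 and 24 h in leaf. All 14 libraries gave 1 in root at 24 h and 0 between 72 and 24 h in leaf. Library size scaling gave 386 in leaf at 72 h, 1 in root at 24 h and 0 between 72 and 24 h in leaf. Legacy dispersion gave 21 in root at 24 h, 0 in root at 72 h, 1 for PEG at 72 h in root minus leaf, 0 for sense over both tissues and 4 for the sense response to PEG. Sense over both tissues gave 5 with RLE scaling, 3 without a treatment block and 0 with 4 pairs only, and sense in root gave 3 without a treatment block.

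For tags apart at 24 h, 2-fold at 20 CPM gave 466 for antisense and 1518 for sense in leaf, and 1810 and 1616 in root. A 4-fold limit at 5 CPM gave 108 and 718 in leaf and 646 and 492 in root, and a pseudocount of 5 gave 18 and 113 in leaf and 115 for antisense in root. Removing adaptor tags and merging tags 1 mismatch apart left every count of called tags within 1.5 times the reported count, and neither was run for the tags apart at 24 h. Setting copy numbers of 1 to 0 changes nothing, since none are listed. Not run, for lack of transcript sequences, were the 39 gene lists with preset or estimated correlation, the ZmPIS tag count, tags of the last CATG site only, tags of several genes, and 1 mismatch to a gene. Depth limits tags of a few copies, which fall below the tested 10 copies in 2 libraries or are unlisted at 1 copy.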

Other observations

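Tests chosen only after the results were seen were the GC and both adaptor tests, the exchanges for sense over both tissues and for sense in root minus leaf, the overlap of leaf and root responses, and the count of tags with shared starts; the tags named in this part were also chosen after their values were seen.

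Leaf tags that rose at 72 h of PEG were often higher in root at 72 h too. Of 435, 249 were higher than control in root in both lines, against a median of 86 and a highest of 109 over 1000 random draws of tags matched on level, and 85 were lower in both lines. Across all 9213 tags of at least 20 CPM on average, however, the leaf and root responses at 72 h correlated at 0.0147 in wild type (rho -0.152) and 0.243 in the sense line (rho 0.172). Of the 145 that fell in leaf, 46 were lower in root in both lines, within the random draws (median 33, highest 49). Called tags also shared sequence starts: 65 of the 580 leaf tags had the same first 14 bases as another called tag. Random draws gave a median of 2 and a highest of 12. These draws came from all tested tags and were not matched on level, so part of the excess may come with abundance. In root at 24 h 6 of 66 did (median 0, highest 2), among them CATGGGTCTTCTTGTGCATCC and CATGGGTCTTCTTGTGCAAAA, and between 72 and 24 h in leaf 3 of 8 did (highest 0).

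Some tags were present or absent by line in nearly every library. CATGAAGACTTCCTTATAGAT had 190 to 204 copies in wild-type leaf and 149 to 235 in wild-type root, none listed in 5 sense libraries, but 104 in the sense root control and 28 and 58 in antisense leaf and root. CATGATCAAATGTGTCAATGA had 21 to 23 copies in sense leaf and 30 and 15 in sense root at 24 and 72 h, none listed in the sense root control, at most 2 in any wild-type library and none listed in antisense libraries. Neither was called by edgeR as reported (adjusted p over both tissues 0.367 and 0.252). Without a low-count filter both passed (3.59e-28 and 1.52e-07), and CATGAAGACTTCCTTATAGAT also passed with DESeq2 (0.000651) and with edgeR without the wild-type or the sense root control (0.039 and 0.0377). The sense minus wild-type differences across 9213 tags correlated at 0.631 between leaf control and leaf at 72 h, but at -0.463 between leaf control and leaf at 24 h and -0.409 between leaf at 24 and 72 h. The 5 tags sought as signs of a vector terminator or of the 3′ adaptor were listed in 0 of 14 libraries.

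More tags separated sense from wild type when the genotypes of 2 pairs, leaf at 24 h and root control, were exchanged, which was picked as the highest of 32 exchanges. It called 47 tags over both tissues against 1 as labelled, with 8811 against 2485 at an unadjusted p under 0.05, and may point to a structure of the libraries beyond genotype, though the level a highest exchange reaches by chance was not tested. GC content of the tags as the whole cause is argued against by its correlation with the exchanged difference, 0.134 in leaf control but -0.251 in root control and -0.242 in root at 24 h. A plain exchange of labels is argued against by CATGATGCCAGTGGCAACTAG (0 copies in wild type and 28 in sense leaf at 24 h, 0 and 121 in root control) and by CATGAAGACTTCCTTATAGAT (204 and 0 in leaf at 24 h), and in root control by CATGAAGTACGGCTGGACGGC (501 and 13) and CATGTTTTAACGTTATCGGAT (211 and 14), which were picked with that pair included. It was left open because only 3 tags were at least 4-fold apart in 1 direction in the 4 other pairs, of which 100% (exact 95% interval 29.2 to 100%) went with the label in leaf at 24 h and 66.7% (9.43 to 99.2%) in root control, and because the differences across tags ran against leaf at 24 h, as given above; a difference between plants or libraries was not tested.

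The tag CATGTCGGACTGTAGAACTCT ranged from 274 to 28912 copies, 105.5-fold, and headed a family of 51 tags within 1 mismatch. All 17 of its bases after CATG equal the reverse complement of adaptor 1, so ligated adaptor is a candidate source. A transcript that PEG moves 1 way is argued against, as the log2 difference between 72 h and control was -3.44 in wild-type and -3.925 in sense leaf but 3.68 in wild-type and 0.54 in sense root. It is among the tags lower in antisense leaf at 24 h (274 against 3091 copies) and among those higher in antisense root (16209 against 1182 copies). Its relatives CATGTCGGACTGTAGAACTGG and CATGTCGGACTGTAGAACTGT are among the tags of smallest p for sense in root minus leaf, which did not pass.

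The tag CATGATGCCAGTGGCAACTAG, listed in all 8 transgenic and no wild-type library, may follow the transgene or a segment linked to it. Splits that take 4 of 7 leaf and 4 of 7 root libraries numbered 1225. Of these, 2 (0.163%) had any tag with at least 5 copies in the chosen 8 and none listed in the other 6. The highest number in another split was 1 tag, as in the real one. The splits chose leaf and root libraries separately, although these are matched on genotype and treatment. Such a tag was thus rare among these splits, but the share does not exclude chance for matched pairs. A seed stock or line background shared by both transgenic lines was not tested and stays open, as does the identity of the tag.

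Other ways to split the libraries were counted for each sense comparison and for the tissues. For sense over both tissues, 11 of 32 exchanges within pairs called at least the 1 tag of the real labels (highest other 47), so chance was not excluded. For sense in root minus leaf and for the sense response to PEG, the real count was 0, which all 32 of 32 exchanges reach whatever they call (highest other 7 and 0), so the count says nothing on chance there. The 10 splits of the leaf libraries and the 10 of the root libraries are too few for a share under 0.05. In leaf all 10 of 10 reach the real 0 whatever they call (highest other 0), and in root 1 of 10 gave the real 1 (highest other 0). For root against leaf, 1 of 64 exchanges, the real one, called as many as 47781, and the highest other called 0. This share lies under 0.05 and is the smallest that 64 exchanges can give. An exchanged pair moves the tissue difference into the error of the fit, so the 0 calls of the others are not separate evidence against chance.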
